A study of Danio rerio with 4 samples.

How the data were processed

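The series holds 4 poly(A) RNA-seq libraries of zebrafish tail tissue at 3 days post fertilization, 2 from siblings and 2 from cpa1 and cpa5 double knockouts of the same parents. Per the labels' protocols, RNA was taken up in Trizol and 500 ng of total RNA went into each library (Hieff NGS Ultima Dual-mode mRNA kit). Groups and replicate numbers come from the sample titles. The genotype label of the controls reads WT, and the titles call them siblings. Siblings of this cross can be heterozygous at either gene, and the labels do not say whether these are, so the sibling level of cpa5, its fold change and the comparison of linked genes are against siblings and not against a known wild type.

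The authors deposited 1 table of the whole series. Per the submitters' processing notes, reads were processed with HISAT2 2.2.1 and DESeq2 1.26.0 against GRCz11. The read counter, the transcript assembler, the annotation release and the use of strand are not given in the sources used here. Per the file headers, the deposited columns give raw read counts per feature and FPKM values per library (fragments scaled by feature length and library size, computed by the authors). The deposited log2 fold change and p-value columns, with their adjusted p-values, are the authors' own comparison of mutant over sibling, whose direction was checked against the counts. The authors' deposited table calls 33 features up and 73 down in a column of its own, in which the largest unadjusted p is 0.049 and the smallest absolute log2 fold change is 0.60. Its adjusted p gives 19 features below 0.05. Features are 17610 Ensembl genes and 2314 assembled models at 2019 loci. The smallest of the features' highest counts over the libraries was 26, so features with low counts are not in the table used here.

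Counts were analysed as deposited. Totals per library were 25623442, 32248878, 24769258 and 35343524 for sibling replicates 3 and 4 and knockout replicates 3 and 4. Libraries of a group were not copies of each other (chi-square per degree of freedom 90 between siblings and 77.7 between knockouts). The main test was edgeR 4.0.16 (quasi-likelihood, TMM normalization, filterByExpr, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter removed no feature. CPM values are counts scaled to library size with TMM factors. With 2 libraries per group the biological coefficient of variation was 32.6%. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the lists with at least 5 measured members, and again with an estimated correlation and with fry. With an estimated correlation camera rests on the residual degrees of freedom, which are few with 4 libraries. A call lost there does not show that correlation between genes caused the loss. cpa1 and cpa5 were left out of the lists. Alternatives were RLE size factors, total counts, other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a fold threshold, the 20 most abundant genes left out, and limma on log2(FPKM + 1). Leaving out a library unbalances the replicate numbers between groups, so those fits mix genotype with replicate number. The design, the lists, the rule for named genes and these alternatives were fixed before the data were examined.

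Genes were named by that rule: cpa1 and cpa5, up to 12 rising and 12 falling genes that passed the adjusted test at a mean of at least 2 CPM with every knockout library on 1 side of every sibling library (0 did), and per list up to 4 members with the smallest p. Other features are named as chosen after their values were seen. Symbols come from the deposited table, and 17185 of the Ensembl identifiers were also found in a separate table of gene names. The planned windows of 5, 10 and 20 Mb around cpa1 and cpa5 were not run, because the gene positions at hand belong to another assembly (GRCz12tu); the order of genes in that assembly was used in their place, for 16200 located genes other than cpa5.

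The tests were tested on simulated data: counts drawn around the fitted means of each replicate number, with dispersions from the fit with the replicate block and 50 features changed at each fold size. Simulated libraries of 1 number are thus pairs by construction, which favours the block in recovery. edgeR made 1 false call and DESeq2 made 4, and with the replicate block edgeR made 43 and recovered 60%, 94%, 100% and 100% of features changed by 1, 2, 3 and 5. In 10 simulated lists of 30 genes lowered by 0.6 on the log2 scale, camera called 10 with either correlation and fry called 7, with 0 false calls in 10 unchanged lists. These simulated genes vary independently, so this recovery does not measure the power of the estimated correlation for the real lists, whose estimated correlations reach 0.81. With 2 libraries per group, no rule for outlying libraries and no count over other splits of the samples applied.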

Results

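RNA from zebrafish (Danio rerio) at 3 days post fertilization was sequenced in 4 libraries, 2 from sibling controls and 2 from fish carrying mutations in both cpa1 and cpa5. These genes code for carboxypeptidase A enzymes, which the exocrine pancreas makes to digest protein. The fish came from parents heterozygous at both genes. Heads were kept for genotyping and the tail tissue was used for RNA. In each group the libraries carry the replicate numbers 3 and 4. Total counts were 25623442 (sibling replicate 3), 32248878 (sibling replicate 4), 24769258 (knockout replicate 3) and 35343524 (knockout replicate 4), over 19924 features made of 17610 Ensembl genes and 2314 assembled models. The labels do not say how many fish each library holds, so p-values measure only the spread between these libraries, which may be technical. Means below are over 2 libraries with their SD, and fold changes are log2 of knockout over sibling with their standard error.

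The targeted gene cpa5 (ENSDARG00000021339) was read at 2079 and 397 counts in the sibling replicates 3 and 4 and at 19 and 15 counts in the matching knockout libraries. This is 46.8 ± 48.4 CPM (normalized counts) in siblings against 0.584 ± 0.211 CPM in double knockouts, and both knockout libraries lay below both sibling libraries. The log2 fold change was -6.34 ± 1.17. The sibling libraries themselves differed from 81.1 to 12.6 CPM, and the edgeR quasi-likelihood test did not pass after adjustment over all features (adjusted p = 1). DESeq2 called the gene at a log2 fold change of -6.33 ± 0.84 (adjusted p = 1.85e-10), the value that the authors' deposited table also lists. The gene cpa1 was not analysed here, so its mutation is taken from the labels alone. The related pancreatic enzyme gene cpa4, named after its values were seen, was read at 24.3 ± 24.5 CPM in siblings and 12.9 ± 10.3 CPM in knockouts (log2 fold change -0.92 ± 1.04, adjusted p = 1), and cpb1, coding for carboxypeptidase B, at 41.1 ± 36.4 and 20.9 ± 13.6 CPM (log2 fold change -0.98 ± 0.86, adjusted p = 1, and 0.45 without sibling replicate 3). The value of 0.45 sets both knockout libraries against sibling replicate 4 alone, so it mixes genotype with replicate number. Between replicate numbers the pancreas enzymes differed by a median of -3.15 (replicate 4 over 3). With each other library left out in turn, cpb1 was at -0.42 to -1.87. Related carboxypeptidase genes can share reads, and how the counting handled such reads is not given in the sources used here.

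**Figure D1:**
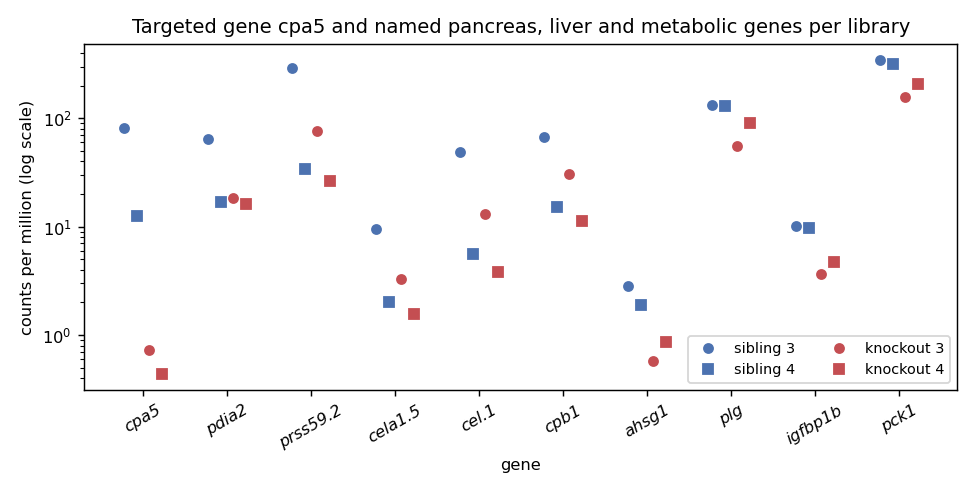
CPM on a log axis for cpa5 and 9 other genes, 1 point per library, blue for siblings, red for knockouts, circles for replicate 3 and squares for replicate 4. cpa5 lay at 81.1 and 12.6 CPM in siblings and at 0.733 and 0.435 CPM in knockouts, while the pancreatic enzyme gene prss59.2 lay highest in sibling replicate 3 (290 CPM).

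Replicate number separated the libraries more than genotype did. The first principal component of log2 CPM held 67.6% of the variance and placed both replicate 3 libraries at negative scores (-51.4 sibling, -49.6 knockout) and both replicate 4 libraries at positive scores (54.8 and 46.2). The second component, with 19.9%, separated sibling replicate 3 (-38.6) from knockout replicate 3 (39.1). Pearson correlations of log2 CPM across features were 0.965 between the replicate 3 libraries and 0.978 between the replicate 4 libraries, against 0.923 between siblings and 0.932 between knockouts. Features are not independent replicates. Mitochondrially encoded genes took 4.93% and 4.78% of the counts in sibling and knockout replicate 3, and 3.01% and 3.2% in replicate 4. Ribosomal protein genes took 5.38% to 5.66% and the 20 most abundant genes 24.8% to 25.95%. The Wilson 95% intervals of these shares reach at most 0.017 percentage points to either side and cover counting error only.

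**Figure D2:**
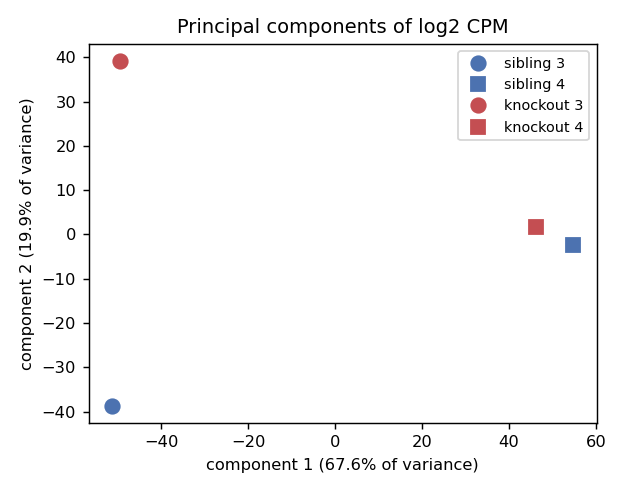
First and second principal components of log2 CPM, 1 point per library, blue for siblings, red for knockouts, circles for replicate 3 and squares for replicate 4. Component 1 holds 67.6% of the variance and parts the replicate numbers, and component 2 holds 19.9%.

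Between replicate numbers, in a comparison and with genes chosen after seeing the data, edgeR with a term for genotype called 1393 features higher in replicate 4 and 1625 higher in replicate 3 (DESeq2 called 2112 in all). The chaperone genes hspb1 and hsph1 were at 35.3 and 3.08 CPM in sibling replicate 3 and at 1080 and 210 CPM in sibling replicate 4, and at 31.4 and 3.12 CPM against 1140 and 221 CPM in knockouts. The heat shock and oxidative stress list as a whole had a median of 0.14 (replicate 4 over 3), with 13 of 32 members called higher and 3 lower. Of 19 cardiomyocyte genes 9 were called higher in replicate 4 and 1 lower, with myl7 at 18 and 2 counts in replicate 3 of siblings and knockouts and 611 and 711 counts in replicate 4. The elastase gene ela2l was at 38.1 and 25.1 CPM in replicate 3 of siblings and knockouts and at 0.254 and 0.203 CPM in replicate 4, and the brush border peptidase gene anpepb at 261 and 216 against 18.7 and 31.3 CPM. The clock genes nr1d1 and per3 had log2 differences of -3.72 ± 0.38 (edgeR adjusted p = 0.00981) and -2.74 ± 0.17 (adjusted p = 0.00429), and of the circadian list 17 of 32 members were called higher in replicate 3 and 4 higher in replicate 4. No list was called between replicate numbers with an estimated correlation (adjusted p = 0.905 with an estimated correlation for heat shock, cardiomyocytes, pancreas enzymes, intestine and clock). This fit leaves 1 residual degree of freedom, on which that test could hardly call any list, so no conclusion is drawn from it.

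Among the genes with the smallest p in their lists, igfbp1b, which codes for a secreted binder of insulin-like growth factors, was at 9.9 ± 0.275 CPM in siblings and 4.21 ± 0.77 CPM in double knockouts (log2 fold change -1.23 ± 0.23). pck1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, was at 333 ± 19.5 and 182 ± 35.8 CPM (-0.87 ± 0.21). The haem-degrading enzyme gene hmox1a was at 15.3 ± 1.8 and 8.63 ± 1.4 CPM (-0.82 ± 0.22), and the matrix metalloproteinase gene mmp13a at 9.75 ± 0.772 and 16.7 ± 4.43 CPM (0.78 ± 0.26). In each of these 4 genes both knockout libraries lay on the same side of both sibling libraries, but none passed the adjusted test (adjusted p = 1). These genes were picked by smallest p, which favours such a separation, so the separation adds no evidence of its own. Over all features 9% lay below and 8.7% above in this way. Chance gives 16.7% each only if the 4 libraries are exchangeable, which their split by replicate number goes against. Without knockout replicate 3 the log2 fold change of mmp13a was 0.48.

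Across the 19924 features edgeR called 0 at adjusted p below 0.05, with a smallest adjusted p of 0.273. At an unadjusted p below 0.05 it listed 100 features, against 996 given by chance alone and 878 with the replicate number as a block. The fit without block counts differences between replicate numbers as spread within groups. Its 0 calls therefore do not show that no feature differs. limma-voom also called 0 and DESeq2 called 19, of which 8 were higher and 11 lower in double knockouts. On simulated counts with 2 libraries per group, 50 features per fold size and all 19924 features in the fit, edgeR recovered 0% of features changed by 1 on the log2 scale, 2% of those changed by 2, 40% of those changed by 3 and 82% of those changed by 5. DESeq2 recovered 12%, 68%, 96% and 98%.

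The 19 features called by DESeq2, which were named after their values were seen, were mostly assembled models and not annotated genes. The authors' deposited table also has 19 features at adjusted p below 0.05, made of 16 assembled models and 3 Ensembl genes. The genes were cpa5, sept15 (septin 15, a filament-forming GTPase) and si:ch1073-340i21.3. sept15 was at 26.3 ± 0.00484 CPM in siblings and 56.2 ± 3.5 CPM in double knockouts (DESeq2 log2 fold change 1.1 ± 0.23, adjusted p = 0.00139). si:ch1073-340i21.3 was read at 0 counts in both sibling libraries and at 45 and 44 counts in the knockout libraries. In 10 of the 16 models, both libraries of a group were at 0 counts.

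The 16 called models came from 12 loci, and at 11 of these the table holds more than 1 model. At the locus that matches doublesex and mab-3 related transcription factor 2a (MSTRG.37962), model 3 had 298 and 386 counts in sibling replicates 3 and 4 and 7 and 12 in knockouts, whereas model 2 had 0 in siblings and 334 and 430 in knockouts. The sums were 298 and 386 against 341 and 442. The locus that matches the ubiquitin ligase pellino homolog 1b (MSTRG.33924) had sums of 358 and 501 in siblings and 395 and 531 in knockouts, with the counts moved from model 2 to model 1. At 4 loci, models were called in both directions. With the counts of each locus summed, the 11 loci had a median absolute log2 fold change of 0.12 and a largest of 0.5, and 0 of them was called by DESeq2. The remaining locus, with 1 model and a match to the large neutral amino acid transporter small subunit 1 (MSTRG.36691), had 749 and 395 counts in siblings and 106 and 108 in knockouts (log2 fold change -2.53 ± 0.5, adjusted p = 0.00415 by DESeq2 over locus sums). Summing per locus was chosen after seeing the data.

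**Figure D3:**
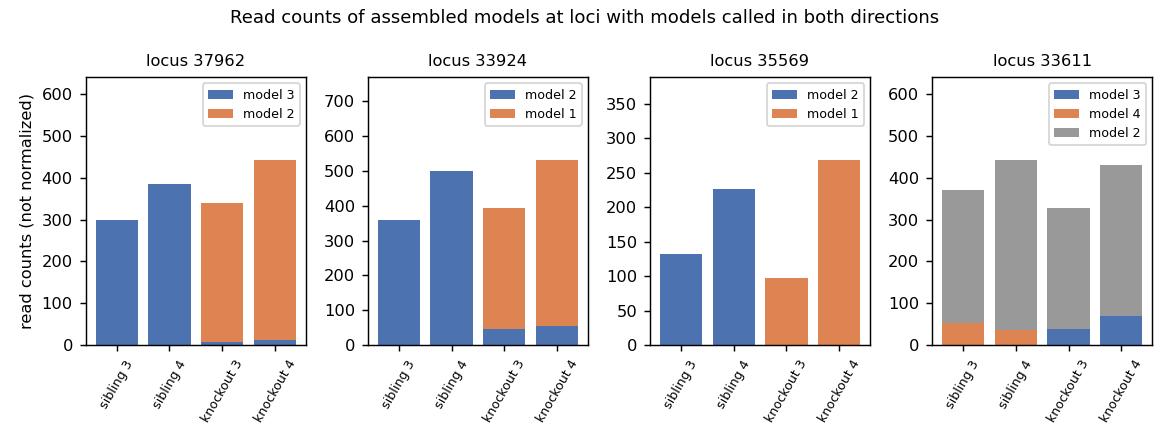
Read counts, not normalized, of the assembled models at 4 loci with models called in both directions, as bars stacked by model for each library. At the doublesex and mab-3 related locus (MSTRG.37962) the bars hold model 3 in siblings (298 and 386 counts) and almost only model 2 in knockouts (334 and 430 counts), with similar bar heights.

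The exocrine pancreas enzymes, the genes for proteases, lipases and amylase that acinar cells secrete, were lower in double knockouts in all 27 measured members, with a median log2 fold change of -1.01. camera with a preset correlation called the list (adjusted p = 0.0112), and this was lost with an estimated correlation (adjusted p = 0.883 with an estimated correlation). The trypsin gene prss59.2 was at 162 ± 181 CPM in siblings and 50.9 ± 34.9 CPM in double knockouts (log2 fold change -1.67 ± 1.12). The bile salt-stimulated lipase gene cel.1 was at 27.1 ± 30.4 and 8.43 ± 6.56 CPM (-1.69 ± 1.17), and pdia2, the pancreatic protein disulfide isomerase gene, at 40.6 ± 33.6 and 17.2 ± 1.6 CPM (-1.24 ± 0.66). Sibling replicate 3 held most of the difference, since prss59.2 was at 290, 34.3, 75.6 and 26.2 CPM in sibling replicates 3 and 4 and knockout replicates 3 and 4. Between libraries of the same number the median difference was -1.19 for replicate 3 and -0.29 for replicate 4, with 17 of 27 members lower in both and 0 higher in both. Without sibling replicate 3 the direction of the list turned (adjusted p = 2.19e-04, higher; prss59.2 and cel.1 both at 0.57, pdia2 at 0.03), and without knockout replicate 4 it turned as well (adjusted p = 0.33), but leaving out 1 library unbalances the replicate numbers. In a comparison chosen after seeing the data, the enzymes were lower in replicate 4 than in replicate 3 by a median log2 value of -3.67 in siblings and -2.18 in knockouts.

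Exocrine pancreas transcription factors were lower in 6 of 7 measured members, with a median log2 fold change of -0.32 (camera adjusted p = 0.0112, and adjusted p = 0.658 with an estimated correlation). The pancreas progenitor gene pdx1 was at 1.41 ± 0.205 CPM in siblings and 0.806 ± 0.115 CPM in double knockouts (-0.81 ± 0.38), and hnf1ba at 15.6 ± 0.783 and 12.5 ± 2.51 CPM (-0.32 ± 0.22). Between libraries of the same number the list's median was -0.49 for replicate 3 and -0.25 for replicate 4. Of the 7 members 5 were lower in both and 0 higher in both. The list's call ended without any 1 of the 4 libraries, and hnf1ba was at -0.13 without knockout replicate 3. Leaving out 1 library unbalances the replicate numbers. Endocrine pancreas markers were not called (10 of 18 lower, median -0.11, adjusted p = 0.0943). Their member ins, coding for insulin, was at 8.27, 7.65, 2.58 and 7.62 CPM in sibling replicates 3 and 4 and knockout replicates 3 and 4, and its log2 fold change of -0.63 was -0.06 without knockout replicate 3. The M14 carboxypeptidase family, to which cpa1 and cpa5 belong, had 6 of 12 other members lower (median -0.01, mean -0.23, adjusted p = 0.715).

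Liver and yolk genes for plasma proteins and lipid carriers were lower in the double knockouts as groups, more so in replicate 3. Of 36 measured hepatocyte genes 32 were lower, with a median log2 fold change of -0.65. plg, the precursor of the clot-dissolving protease plasmin, was at 131 ± 2.65 CPM in siblings and 73.5 ± 25.3 CPM in double knockouts (-0.83 ± 0.29). The plasma protease inhibitor gene a2ml was at 416 ± 85.6 and 271 ± 38.3 CPM (-0.62 ± 0.23), and ahsg1, coding for a fetuin, at 2.36 ± 0.639 and 0.724 ± 0.206 CPM (-1.68 ± 0.41). camera with a preset correlation called the hepatocyte list (adjusted p = 4.10e-13), and the call was lost with an estimated correlation of 0.37 (adjusted p = 0.658 with an estimated correlation). That test also rests on few residual degrees of freedom, so the loss cannot be put down to the correlation alone. The hepatocyte list was the 1 list of the 10 called that kept its call without any 1 library. Leaving out 1 library unbalances the replicate numbers, between which this list differed by a median of 0.72 (replicate 4 over 3). plg was at -0.52 without knockout replicate 3 and a2ml at -0.39 without sibling replicate 4. In 7 of the 36 genes both knockout libraries lay below both sibling libraries. Over all features this held for 9%. The 16.7% given by chance needs exchangeable libraries, which the split by replicate number goes against. The median difference of the hepatocyte list was -1.01 between the replicate 3 libraries and -0.39 between the replicate 4 libraries. Lists of some other tissues were also lower in knockout than in sibling replicate 3: erythrocytes by a median of -0.95, intestinal epithelium by -0.54, cartilage, bone and notochord by -0.6 and the hatching gland by -3.45, against 0.01, 0.14, 0.17 and -1.43 between the replicate 4 libraries. Others were not, with replicate 3 medians of 0 for skeletal muscle and for epidermis, 0.03 for vascular endothelium, 0.04 for pigment cells and for glia, and 0.12 for neurons.

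Genes of the yolk syncytial layer and apolipoproteins, which package yolk lipid for the embryo, were lower in 18 of 18 measured members (median -0.47, adjusted p = 1.15e-07, and adjusted p = 0.658 with an estimated correlation). apoa2 was at 4840 ± 1110 CPM in siblings and 3330 ± 1260 CPM in double knockouts (-0.54 ± 0.34), and apoc2, a cofactor of lipoprotein lipase, at 674 ± 21.7 and 477 ± 132 CPM (-0.5 ± 0.24). The list shares 2 genes with the hepatocyte list. All 18 members were lower in the knockout within both replicate numbers, with medians of -0.69 for replicate 3 and -0.33 for replicate 4. The list's call ended without sibling replicate 4 and without knockout replicate 3. Leaving out 1 library unbalances the replicate numbers, between which this list differed by a median of 0.65 (replicate 4 over 3). Without knockout replicate 3 apoa2 was at -0.2 and apoc2 at -0.24, and without sibling replicate 4 apoa2 was at -0.28.

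**Figure D4:**
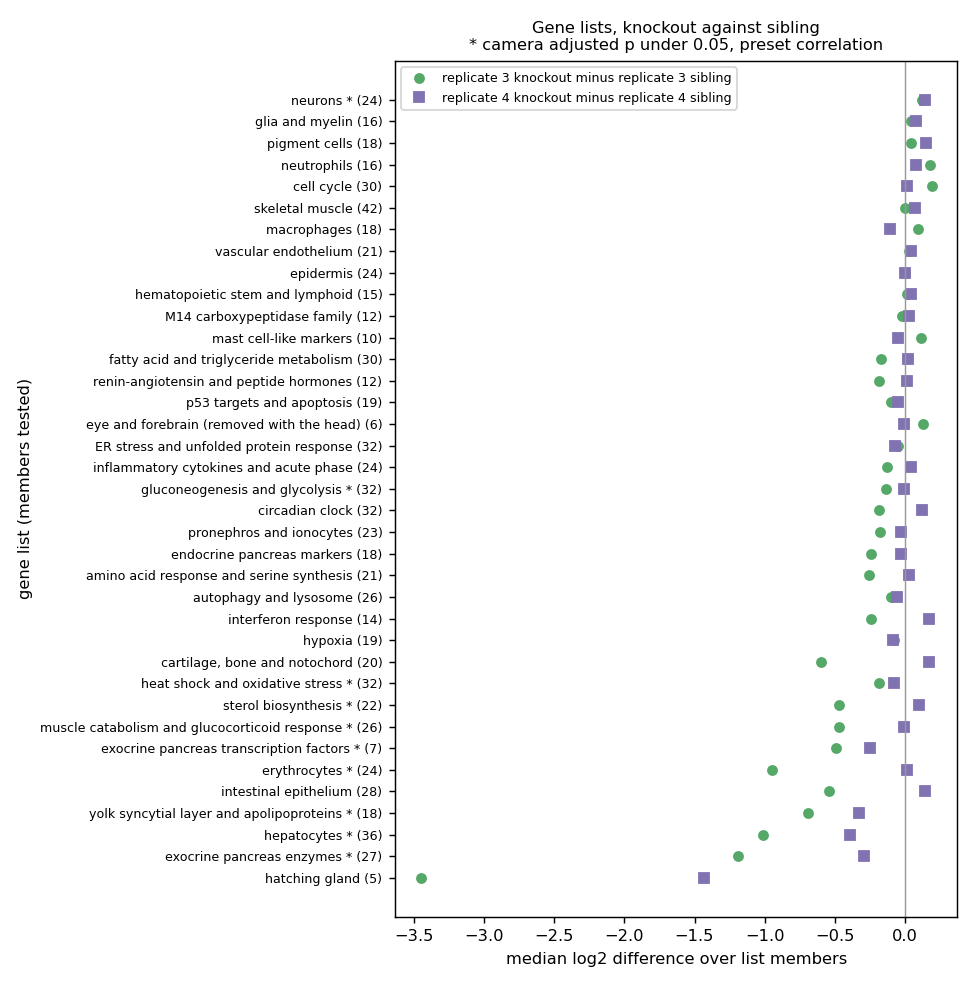
Median log2 difference of knockout minus sibling over the members of each gene list, circles for the replicate 3 libraries and squares for the replicate 4 libraries, with the number of members in parentheses and an asterisk where camera with a preset correlation gave an adjusted p below 0.05. Hepatocyte, yolk and exocrine enzyme lists lie below 0 for both replicate numbers, and the 24 neuron genes lie just above 0.

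Lists that hold genes of glucose production had medians below 0 between the replicate 3 libraries and near 0 between the replicate 4 libraries. The list of muscle catabolism and glucocorticoid response genes was lower in 24 of 26 members (median -0.28, adjusted p = 9.18e-06, and adjusted p = 0.658 with an estimated correlation). Its leading members igfbp1b, pck1, g6pca.2 and fbp1b are a gene for a binder of insulin-like growth factors and genes of hepatic glucose production, not of muscle breakdown, and the hepatocyte genes were lower in the same libraries (median -0.65). g6pca.2, the catalytic subunit of glucose-6-phosphatase, was at 238 ± 65 CPM in siblings and 157 ± 4.23 CPM in double knockouts (-0.6 ± 0.25). Genes of gluconeogenesis and glycolysis, which share 4 members with that list, were lower in 24 of 32 (median -0.08, mean -0.18, adjusted p = 0.00175, and adjusted p = 0.676 with an estimated correlation). slc2a2, the liver and pancreas glucose transporter, was at 42.2 ± 2.85 and 29.5 ± 4.36 CPM (-0.52 ± 0.18), and the liver pyruvate kinase gene pklr at 30.6 ± 6.64 and 21 ± 0.524 CPM (-0.54 ± 0.21). The median of the muscle catabolism list was -0.47 between the replicate 3 libraries and that of the gluconeogenesis list -0.14, against -0.01 for both between the replicate 4 libraries. Without sibling replicate 3 neither list was called, both at an adjusted p of 0.676, and the gluconeogenesis list was also lost without knockout replicate 4. g6pca.2 was at -0.29, fbp1b at -0.15 and pklr at -0.3 without sibling replicate 3. In that fit igfbp1b was at -1.20, pck1 at -0.81 and slc2a2 at -0.59. Leaving out 1 library unbalances the replicate numbers. The list medians do not hold for every member. Between the replicate 4 libraries igfbp1b was at 306 counts in the sibling and 164 in the knockout, and pck1 at 10070 and 7165.

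Sterol biosynthesis genes were lower in 19 of 22 members (median -0.21, adjusted p = 0.0112, and adjusted p = 0.676 with an estimated correlation). Their median was -0.47 between the replicate 3 libraries but 0.1 between the replicate 4 libraries, with 7 of 22 members lower in both. dhcr7, coding for a reductase of cholesterol synthesis, was at 23.2 ± 0.0417 CPM in siblings and 16.6 ± 4.72 CPM in double knockouts (-0.48 ± 0.26). Heat shock and oxidative stress genes were lower in 26 of 32 members (median -0.18, adjusted p = 0.0112, and adjusted p = 0.658 with an estimated correlation), led by hmox1a and by cat, coding for catalase, at 130 ± 4.94 and 97.2 ± 19.2 CPM (-0.42 ± 0.21). The sterol list turned direction without sibling replicate 3 and the heat shock list without knockout replicate 3, but leaving out 1 library unbalances the replicate numbers. Each also lost its call without 1 other library, the sterol list without knockout replicate 3 and the heat shock list without sibling replicate 4. dhcr7 was at -0.22 and cat at -0.23 without knockout replicate 3.

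Erythrocyte genes were lower in 22 of 24 members (median -0.4, adjusted p = 1.03e-04, and adjusted p = 0.658 with an estimated correlation). The carbonic anhydrase gene cahz was at 27.8 ± 2.61 CPM in siblings and 21.1 ± 6.31 CPM in double knockouts (-0.4 ± 0.27), and nt5c2l1 at 12.5 ± 2.54 and 7.32 ± 3.87 CPM (-0.77 ± 0.44). Haemoglobin genes took 0.06% of the counts in knockout replicate 3, against 0.14% and 0.17% in sibling replicates 3 and 4 and 0.18% in knockout replicate 4. The list was not called without sibling replicate 3 or without knockout replicate 3, with adjusted p up to 0.729, and cahz was at -0.12 and nt5c2l1 at -0.32 without knockout replicate 3. Neuron genes were higher in 21 of 24 members by a small amount (median 0.15, adjusted p = 0.0112, and adjusted p = 0.658 with an estimated correlation). Their estimated correlation was -0.03, and the unadjusted camera p went from 0.00229 to 0.0774. Correlation between these genes thus does not account for the lost call. The vesicular glutamate transporter gene slc17a6b was at 12.2 ± 0.676 CPM in siblings and 14.4 ± 2.16 CPM in double knockouts (0.24 ± 0.2), and gad1b, which makes the transmitter GABA, at 16.1 ± 1.12 and 18.4 ± 1.41 CPM (0.2 ± 0.18). The neuron call was lost without sibling replicate 3, without sibling replicate 4 and without knockout replicate 4, with adjusted p up to 0.229, and slc17a6b was at 0.08 and gad1b at 0.12 without knockout replicate 3.

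Apart from the heat shock and oxidative stress list, stress and immune lists were not called by camera in the main fit. Some were called on FPKM values or when 1 library was left out, which unbalances the replicate numbers. Genes of ER stress and the unfolded protein response were lower in 24 of 32 members by a median of -0.06 (adjusted p = 0.195), with chac1 at 113 ± 3.38 CPM in siblings and 93.5 ± 23.7 CPM in double knockouts (-0.28 ± 0.23, and -0.04 without knockout replicate 3). Inflammatory cytokine and acute phase genes were lower in 13 of 24 members (median -0.07, mean 0.03, adjusted p = 0.343), neutrophil genes in 8 of 16 (adjusted p = 0.679), macrophage genes in 7 of 18 (median 0.02, mean -0.01, adjusted p = 0.984) and mast cell-like markers in 6 of 10 (median -0.03, mean 0.01, adjusted p = 0.964). The neutrophil chemotaxin gene lect2l was at 41.1 ± 5.45 CPM in siblings and 24.1 ± 3.21 CPM in double knockouts (-0.77 ± 0.2, adjusted p = 1). For the inflammatory, macrophage and mast cell-like lists the median and the mean differ in sign, and camera took the sign of the mean. Adjusted p was 0.1 for the amino acid response, 0.12 for autophagy and lysosome, 0.545 for p53 targets and for the interferon response, 0.872 for hematopoietic stem and lymphoid genes and 0.173 for hypoxia.

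Other tissues and programmes were not called either by camera after edgeR normalization. Adjusted p was 0.0562 for the hatching gland (5 of 5 lower, median -1.58), 0.0597 for the cell cycle (24 of 30 higher, median 0.07) and 0.0764 for intestinal epithelium (25 of 28 lower, median -0.43). The hatching gland and intestinal epithelium lists were called, lower, with DESeq2 (adjusted p = 0.0476 and 4.59e-04), with total counts (0.0275 and 0.0265) and on FPKM values (0.018 and 0.00468). The cell cycle list was called, higher, with limma-voom (0.0341) and on FPKM values (0.0118). With the replicate number as a block all of these lists were called in the same directions. Adjusted p by camera was then 2.81e-04 for hatching gland, 0.0228 for intestinal epithelium and 0.0283 for the cell cycle. With an estimated correlation adjusted p was 0.658 for hatching gland and cell cycle and 0.798 for intestinal epithelium. For the other lists it was 0.136 for glia and myelin, 0.218 each for skeletal muscle, pigment cells, fatty acid metabolism and cartilage, bone and notochord, 0.219 for pronephros and ionocytes and 0.342 for the renin-angiotensin and peptide hormone list. It was 0.497 for vascular endothelium, 0.757 for eye and forebrain genes, 0.835 for the circadian clock and 0.94 for epidermis. For eye and forebrain genes the median (-0.06) and the mean (0.03) differed in sign, and for epidermis camera gave higher while the mean was -0.02. No member of any list passed the edgeR test adjusted over all features, and 0 members passed when adjusted over the list alone.

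Whether genes linked to cpa1 and cpa5 differ was asked because double knockouts of a cross are homozygous for the chromosome around the mutations. cpa1 and cpa5 neighbour each other in the GRCz12tu annotation, which was used only for gene order. No gene on their chromosome passed the adjusted edgeR test. At an unadjusted p below 0.01, 3 of 514 genes on that chromosome were listed against 5 of 15686 elsewhere (odds ratio 18.4, 95% interval 2.85 to 94.8, two-sided Fisher's exact test p = 0.00158). By DESeq2, chosen after seeing the data, it was 4 against 12 (odds ratio about 10, 95% interval 2.4 to 33.9, Fisher's exact test p = 0.00135). The genes, named after their values were seen, were sept15, the neurotrophin receptor gene ntrk3a and cib1, a calcium-binding protein gene. ntrk3a was at 3.78 ± 0.491 CPM in siblings and 8.53 ± 0.752 CPM in double knockouts (1.17 ± 0.22), and cib1 at 9.72 ± 0.79 and 4.22 ± 1 CPM (-1.2 ± 0.26). By distance from cpa5 they ranked 167 (sept15), 182 (ntrk3a) and 387 (cib1) among the located genes of the chromosome, and 0 of the nearest 100 genes was listed by edgeR and 1 by DESeq2. Genes are not independent and the edgeR comparison rests on 8 listed genes.

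Gene ontology and pathway terms paired with features in the deposited table gave 0 enriched terms, since edgeR called 0 features. With the 23 annotated features at an unadjusted p below 0.01 (9 higher, 14 lower) in place of called ones, 0 of 15701 terms passed Fisher's exact test. By camera over the same terms, chosen after seeing the data, 99 terms passed (50 lower, 49 higher). The lower ones included negative regulation of complement activation by the lectin pathway (19 of 21 genes lower, median -0.57, adjusted p = 1.14e-07) and steroid biosynthesis (18 of 18 lower, median -0.41, adjusted p = 2.18e-04). The terms were not split by replicate number. The sterol biosynthesis list had medians of -0.47 between the replicate 3 libraries and 0.1 between the replicate 4 libraries, with 7 of 22 members lower in both. Among the higher terms was spinal cord motor neuron cell fate specification (39 of 139 lower, median 0.1, adjusted p = 0.00246). All 99 terms were lost with an estimated correlation (adjusted p = 0.999 with an estimated correlation, the smallest of any term). That test rests on few residual degrees of freedom, so the loss does not show that correlation between genes made these calls.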

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

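Several alternatives here were chosen after seeing the data: sums per locus, Ensembl genes alone, sets of nearest genes, camera over terms, and the fits other than edgeR without block for the chromosome. The planned windows in Mb were not run. The count of 0 called features stayed 0 with RLE factors, total counts, either filter, limma-voom, FPKM values, the fold threshold and without the 20 most abundant genes, and was 0 to 0 without any 1 library, where the lone library of a group is assumed to vary like the other. The filter removes nothing here, so leaving it out tests nothing. DESeq2 called 19 features, 4 after sums per locus and 3 over Ensembl genes alone. For cpa5 the log2 fold change was -6.33 in DESeq2, with or without sums per locus or assembled models, and past the threshold there, and -4.44 to -7.13 without any 1 library, never past it in edgeR (adjusted p 0.172 to 1). It was -5.80 in limma-voom and -3.92 on FPKM values, also not past the threshold.

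The labels do not say that the replicate numbers pair the libraries. The difference between numbers 3 and 4 in siblings correlated with that in knockouts at 0.62 over features, which are not independent. With the replicate number as a block edgeR called 3 features, all assembled models (1 higher, 2 lower), 0 after sums per locus, and 1 over Ensembl genes alone, cpa5, at -6.07 (adjusted p = 0.0482). Over all features cpa5 was at -6.04 with the block (adjusted p = 0.0771). The coefficient of variation was then 15.4%. Of the lists 13 were called with the block, among them exocrine enzymes, lower (adjusted p = 4.58e-10), and 0 with an estimated correlation (adjusted p = 0.856 for the enzymes). The blocked fit leaves 1 residual degree of freedom, so the absence of calls with an estimated correlation decides nothing. On the chromosome of cpa5, 15 of 514 genes against 151 of 15686 elsewhere were then at an unadjusted p below 0.01 (odds ratio 3.09, 95% interval 1.68 to 5.31), 2 of them among the nearest 100.

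Of the 10 called lists, 10 stayed called under every other scaling, filter and test except an estimated correlation (0) and fry (0); other scalings and tests added hatching gland and intestinal epithelium (total counts, DESeq2, block, FPKM values), cell cycle (limma-voom, block, FPKM values) and the amino acid response (FPKM values), and the count ran from 8 to 12 without any 1 library. Of the 10 lists only 4, 6, 5 and 6 then stayed called without sibling replicates 3 and 4 and knockout replicates 3 and 4, with exocrine enzymes turned among the 4, and the rest of the count was other lists. Lists turned without sibling replicate 3 for exocrine enzymes (2.19e-04), intestinal epithelium (0.0216), sterol biosynthesis (0.676) and the clock (0.0069), without knockout replicate 4 for exocrine enzymes (0.33), and without knockout replicate 3 for cartilage, bone and notochord (0.0149) and heat shock (0.844), all as adjusted p. Over the 4 libraries left out, adjusted p ran from 6.37e-18 to 0.33 for exocrine enzymes, 4.25e-08 to 0.812 for intestinal epithelium, 1.74e-05 to 0.648 for cartilage, bone and notochord, 4.29e-05 to 0.676 for sterol biosynthesis, 0.00291 to 0.213 for the clock and 2.26e-04 to 0.844 for heat shock. Leaving out 1 library also unbalances the replicate numbers between groups. Genes on the chromosome of cpa5 at an unadjusted p below 0.01 numbered 3 in edgeR and 4 by DESeq2, and in edgeR 0, 2 and 3 among the nearest 100, 200 and 400. Terms numbered 99 by camera. The cause of these differences was not tested.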

Other observations

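The tests in this part were chosen after the main results were seen, as were the genes it names. The bounds for reading the further hepatocyte genes were set before their values were seen, and the use of the standard error beside them was added after.

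Libraries of both genotypes split by replicate number, with 3018 features called by edgeR with a term for genotype. Among them were 23 of 27 pancreas enzymes, 16 of 28 intestinal and 17 of 32 clock genes lower in replicate 4 and 9 of 19 cardiomyocyte genes higher. No list was called with an estimated correlation, but that test had 1 residual degree of freedom and could hardly call any. Endocrine markers and exocrine transcription factors had medians of 0.28 and 0.26 (replicate 4 over 3), while the enzymes had -3.15. The insulin gene ins was at 0.68 ± 0.42 and pdx1 at -0.29 ± 0.31, so no drop as large as that of the enzymes was seen in them. Several members of both lists are also expressed in nerve, liver or gut. Their medians therefore cannot exclude a loss of exocrine pancreas tissue from the replicate 4 pieces, which stays open. More heart tissue in the replicate 4 pieces may account for the cardiac genes alone. The cardiomyocyte list had a median of 1.13, with 0.74 in siblings and 1.5 in knockouts, and several of its genes are also expressed in skeletal muscle, so this stays open. The labels give 3 days post fertilization for all libraries, and differences in stage, light or temperature between collections remain untested.

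At 4 of the 12 loci with assembled models called by DESeq2, models were called in both directions, and at the other 8 loci 1 model was called. A change of the whole locus as large as that of its models is argued against, since at 11 of 11 loci with several models every called model lay outside the 95% interval of the locus sum. At the 4 loci with models called in both directions a sum could not follow both, so this test carries less weight there. Reads counted under different models of 1 locus remain a candidate explanation: the sums had a median absolute log2 fold change of 0.12, against 8.48 for the called models. Of the 16 called models, 10 were at 0 counts in both libraries of a group, where the size of a fold change is poorly determined. Whether the models differ by a linked sequence variant, by splicing or by the assembly was not tested.

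In 54 further hepatocyte genes the median log2 difference between the replicate 3 libraries was -0.69 (standard error 0.18), and 50 were lower. Of the 54, 32 were lowest of all 4 libraries in knockout replicate 3, where chance gives 25% if the libraries are exchangeable. Such values would be seen with less liver RNA in that piece. Some other tissues were lower in the same library, with 2 against 18 counts of the heart gene myl7, 7 against 115 of the hatching gland gene he1.1 and a median of -0.95 for erythrocytes, while skeletal muscle and epidermis had medians of 0, vascular endothelium 0.03, neurons 0.12 and endocrine pancreas -0.24. This compares 1 library with 1 library, so a smaller liver, a different line of dissection and a difference in stage all stay open. Between the replicate 4 libraries the median was -0.15 (standard error 0.06, 38 of 54 lower), which taken alone meets the bound set beforehand against less liver RNA (a median above -0.2). It does so by less than 1 standard error, an allowance made only once the value was known, and the error over correlated genes does not measure the spread between libraries (estimated correlation 0.37 in the fixed list), so the question is left open.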
